A study of Homo sapiens with 6 samples.

How the data were processed

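RNA immunoprecipitation and sequencing (RIP-seq) recovers a protein with an antibody, together with the RNA bound to it, and sequences that RNA. Per the labels, 6 libraries were made from wild-type HEK293T cells in 2 RIP experiments, RIP-1 and RIP-2. Each experiment had an anti-SF3B4 library, a library from non-specific IgG and an input library, so each of the 3 groups had 2 libraries. Per the labels' protocols, a commercial RIP kit was used, ribosomal RNA was removed from the immunoprecipitated and input RNA, and libraries from a low-input kit were sequenced as paired-end reads of 150 bp. Per the submitters' processing notes, cutadapt 1.9.3 and HISAT2 2.0.4 were used with the genome build hg19.

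The deposited values are lists of peaks, called once per RIP experiment and not on pooled experiments. The peak names carry the prefix of MACS, a peak caller made for chromatin immunoprecipitation, and its version and settings are not given in the sources used here. Whether the IgG or the input library served as the control is not given either. Each call was divided by the authors into a list named mRNA and a list named NotExon, here called the mRNA list and the non-exon list; what the names mean is not defined in the sources used here. The peak numbers of the 2 lists of an experiment complete each other without gaps, up to 36757 in RIP-1 and 144374 in RIP-2, and no peak stood in both. The intervals of the mRNA lists carry a strand, and a large part of the overlapping pairs of RIP-1 and RIP-2 had identical edges, so they may not be the peaks as called. The non-exon lists carry whole peaks without a strand.

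The deposited score of each peak behaved as 10 times the negative log10 of the p-value that MACS gives, with a floor of 50 and many strong peaks at 3100. That value looked like a cap, although some peaks scored higher, so the order of the strongest peaks by score is uncertain. The non-exon lists also hold, in the column order of a MACS table, the length, the fold enrichment over the control as deposited by the authors, and a false discovery rate (FDR) in percent. MACS estimates that FDR by exchanging the immunoprecipitated library and the control. These columns have no header, so their meaning was taken from the values and their order. Lengths showed that non-exon positions count from 1 with both ends included. For the mRNA lists the counting base is unknown, and positions are given as deposited, with an uncertainty of 1 bp.

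The lists give no read counts, so the depth of every library is unknown and values are not set against depth. With 1 list per experiment, no error across replicates can be put on a value of a list. Shares of peaks are given with 95% Wilson confidence intervals, which treat peaks as independent and cover counting error only.

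The main comparison was the overlap of the RIP-1 and RIP-2 lists, since the design text of the series says that the repeated experiments were compared to exclude non-specific reads. A RIP-1 peak was called shared when it overlapped a RIP-2 peak of the same kind of list by at least 1 bp, on the same strand where a strand is given. Chance was estimated by moving every peak of 1 experiment by a random distance of 1 to 10 kb, 1000 times, in a one-sided permutation test whose smallest possible p is 0.001. Moved peaks are not kept inside exons, so if the mRNA lists hold only exon segments, this chance level leaves out the overlap that exon structure alone would give. Strength was compared across shared peaks by Spearman correlation and by Pearson correlation of log10 values. Shared and unshared peaks of a list were compared by a two-sided permutation test of the difference of medians. These tests used 100000 resamples for the mRNA lists and 10000 for the non-exon lists. Peaks are not independent replicates, and every p describes these 2 experiments and not a population of experiments.

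The comparisons, the overlap settings and the rule for the peaks named were fixed before the data were examined. That rule takes the 10 shared mRNA-list peaks with the highest lower score of the 2 experiments, the 5 strongest unshared peaks of each mRNA list, and the 5 places with the most shared non-exon peaks, as positions where genes cannot be named. For the last part, windows of 100 kb stood in for genes. The gene table at hand is for another genome build than hg19, so no gene name was assigned. Gene lists, transcript regions, distances to 3′ splice sites and the METTL16 consensus sequence need an annotation or a sequence of hg19 and were not analysed here. Comparisons of the non-exon lists beyond their overlap, of chromosomes and of 10 classes of score were added after the lists were seen.

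Alternative settings were a stricter overlap, the upper 50% by score, lists of equal length, strand ignored, merged intervals and longer moves for chance. Added after seeing the data were thresholds from the FDR, pieces of at least 100 bp, chromosomes 1 and 13 left out, longer moves for the non-exon lists and the fold enrichment in place of the score. Calculations were done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0. The overlap code was checked against bedtools 2.31.1, which gave the same 703 and 4679 shared peaks. It was also tested on simulated data. With 500 shared peaks placed in simulated mRNA lists, the excess over chance was 491, and with none placed it was 1.80. With 2000 placed in simulated non-exon lists, the excess was 1718, and with none placed it was 76.1, with a permutation p of 0.0299, under the 0.05 threshold although no shared peak had been placed. Over 40 simulations per kind of list with none placed, p was under 0.05 in 1 for the mRNA lists and in 3 for the non-exon lists. The simulated lists were made by moving RIP-2 peaks much farther than 10 kb, which removes local crowding. In the simulated mRNA lists with none placed the chance mean was 23.2, against 67.5 in the data. The simulations therefore do not show the error rate of the test on lists crowded as the real ones are.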

Results

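SF3B4 is a subunit of SF3b, the part of the U2 small nuclear ribonucleoprotein that engages the branch site of introns during splicing. METTL16, named with it in the title of the series, is an RNA methyltransferase that makes N6-methyladenosine. RNA bound to SF3B4 was mapped by RIP-seq in wild-type HEK293T, a human cell line derived from embryonic kidney that carries the SV40 large T antigen. The series comprised 6 libraries in 3 groups (anti-SF3B4, IgG and input) of 2 libraries each, from 2 RIP experiments. The data analysed were 4 peak lists, an mRNA list and a non-exon list for each experiment. These follow the authors' names for the lists (mRNA and NotExon), which the sources used here do not define, so whether a peak lies in an exon was not checked. The IgG and input libraries enter only through the peak calls. Library depth is unknown, and each list stands for 1 experiment without replicate error.

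The RIP-1 call held 36757 peaks and the RIP-2 call 144374. The mRNA lists were close in length, with 10960 peaks in RIP-1 and 10280 in RIP-2. The non-exon lists were not, with 25797 peaks in RIP-1 and 134094 in RIP-2. Peaks of the mRNA list made up 29.8% of the RIP-1 call (95% CI 29.4 to 30.3) and 7.12% of the RIP-2 call (95% CI 6.99 to 7.25). The RIP-1 mRNA list covered 5.30 Mb and the RIP-2 mRNA list 2.99 Mb, while the non-exon lists covered 24.2 Mb and 87.1 Mb. Median widths in the mRNA lists were 216 bp in RIP-1 and 160 bp in RIP-2, and in the non-exon lists 710 bp and 564 bp. The plus strand carried 51.2% of the RIP-1 and 51.8% of the RIP-2 mRNA-list peaks.

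Median scores of the mRNA lists were nearly equal, at 79.9 in RIP-1 (interquartile range 61.3 to 122) and 79.6 in RIP-2 (62.2 to 114), but the strong end differed. A score of 3100 or more was reached by 58 RIP-1 and 2 RIP-2 peaks of the mRNA lists. In the non-exon lists the median score was 66.9 in RIP-1 and 80.6 in RIP-2. The median fold enrichment there was 6.55 in RIP-1 (interquartile range 5.39 to 7.68) and 8.19 in RIP-2 (6.75 to 9.64). By the FDR in the lists, few of these peaks passed a 5% limit. In RIP-1, 175 of 25797 non-exon peaks had an FDR of 5% or less (0.678%, 95% CI 0.585 to 0.786) and 94.1% had an FDR of 100%. In RIP-2, 0 of 134094 reached 5%, the lowest FDR was 68.3%, and 41.6% of the peaks had an FDR of 100%. The depths and controls behind the calls are unknown, so the values of RIP-1 and RIP-2 are set side by side without a test.

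Peaks of the mRNA lists were densest on chromosomes 19 and 17 in both experiments, and the excess was larger in RIP-1. Chromosome 19 carried 11.2 mRNA-list peaks per Mb in RIP-1 and 5.04 in RIP-2, against means over all chromosomes of 3.54 and 3.32. It held 6.07% of the RIP-1 list (95% CI 5.64 to 6.53) and 2.90% of the RIP-2 list (95% CI 2.59 to 3.24). Chromosome 17 carried 8.04 peaks per Mb in RIP-1 and 4.92 in RIP-2. The sparse chromosome 13 had nearly equal values of 2.10 and 2.02. In the non-exon lists the experiments ranked the chromosomes differently. RIP-1 non-exon peaks were densest on chromosomes 17 and 19, with 11.99 and 11.89 per Mb against a mean of 8.34. RIP-2 non-exon peaks were densest on chromosomes 1 and 3, with 57.5 and 51.2 per Mb against a mean of 43.3, and chromosome 19 had 31.4 per Mb.

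**Figure D1:**
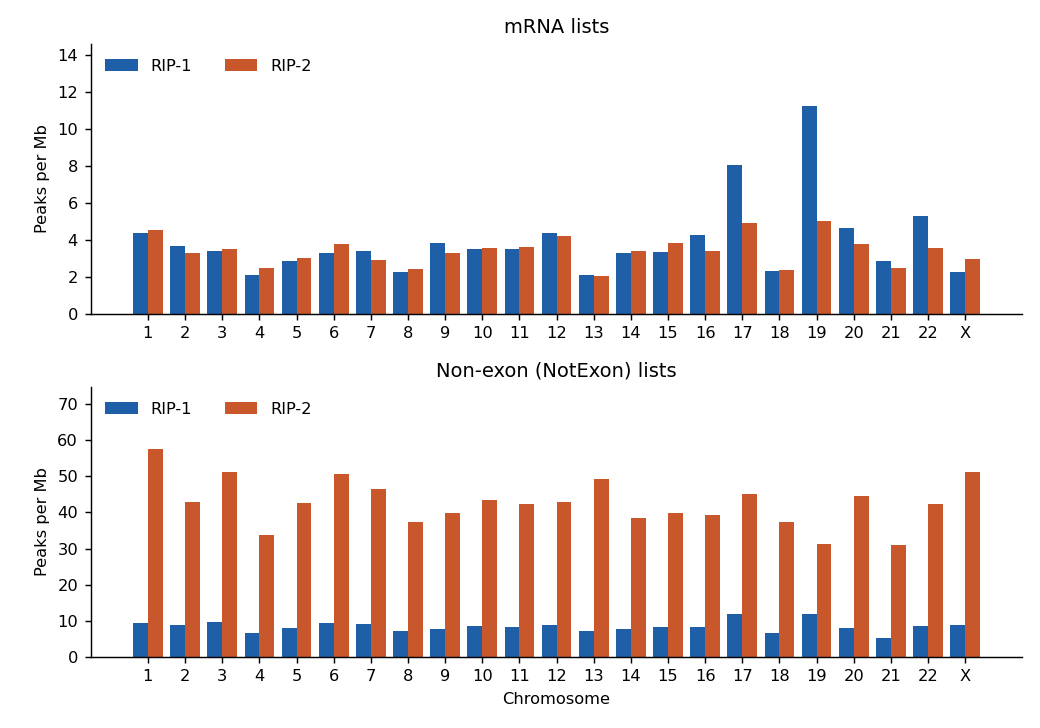
Peaks per Mb (vertical axis) on each chromosome (horizontal axis), for the mRNA lists in the upper panel and the non-exon lists in the lower panel, with blue bars for RIP-1 and orange bars for RIP-2. Chromosome 19 stands out in the RIP-1 mRNA list at 11.2 peaks per Mb against 5.04 in RIP-2, and the RIP-2 non-exon list lies above that of RIP-1 on every chromosome drawn.

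At the scale of windows of 1 Mb the lists of both experiments rose and fell together. Across 2902 windows, the numbers of mRNA-list peaks of RIP-1 and RIP-2 correlated with a Spearman rho of 0.675, and those of the non-exon peaks with a rho of 0.646. The mRNA and non-exon lists of the same experiment correlated with a rho of 0.582 in RIP-1 and 0.373 in RIP-2. The RIP-1 mRNA list and the RIP-2 non-exon list gave a rho of 0.304. Each of these 5 relations had a permutation p of 1e-04, also after Benjamini-Hochberg adjustment, which is the smallest that 10000 resamples can give. Windows are not independent replicates, and neighbouring windows resemble each other.

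The overlap of the mRNA lists asks which segments were called as peaks of the anti-SF3B4 library in both experiments. Of the 10960 RIP-1 peaks, 703 overlapped a RIP-2 peak (6.41%, 95% CI 5.97 to 6.89), and of the 10280 RIP-2 peaks, 710 overlapped a RIP-1 peak (6.91%, 95% CI 6.43 to 7.41). After random moves of 1 to 10 kb, 67.5 RIP-1 peaks overlapped on average (95% range 53 to 83), so the observed number was 10.4 times chance (permutation test, one-sided, p = 0.001, the smallest possible). The factor depends on how overlap and chance are defined, and was 50.03 when at least 50% of both peaks had to overlap. Of the 710 overlapping pairs, 77.6% had the same start and 75.8% the same end in both lists, 87.5% had at least 1 edge in common and 65.9% had both. What set these common edges is not given in the sources used here, and the random moves do not keep them. Part of the factors of 10.4 and 50.03 may therefore come from the edges, and their size was not read as reproducibility of SF3B4 binding.

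The 10 shared peaks with the highest lower score had scores of 142 to 256 in RIP-1 and of 144 to 287 in RIP-2. The first lay on the plus strand of chromosome X from 24766427 to 24766577 (hg19, as are all positions here), with the same edges in both lists and scores of 256 in RIP-1 and 185 in RIP-2. The second lay on the minus strand of chromosome 8 from 124382060 to 124382264, with scores of 183 and 287. The next was on the minus strand of chromosome 10 from 126847203 to 126847384, with scores of 176 and 213, followed by a plus-strand segment of chromosome 10 from 70530962 to 70531202 with 238 and 171. A minus-strand segment of chromosome 5 from 131533898 to 131533964 scored 170 and 224. On the minus strand of chromosome 7, a RIP-1 peak from 97920961 to 97921872 (score 192) overlapped a RIP-2 peak from 97921450 to 97922764 (score 167). The other 4 were on chromosome 1 from 68947728, on chromosome 19 from 37642632, and on chromosome 5 from 131892629 and from 78981021, by their RIP-1 starts. The mRNA lists give no FDR, but in the non-exon lists of the same calls no RIP-1 peak with a score under 402 had an FDR of 5% or less, and every RIP-2 peak with a score above 89.5 had an FDR of 100%. MACS takes this FDR from the control library, which is unknown here, and in RIP-2 the FDR rose with the score, so it was not used to rank these peaks. By score, the 10 ranked from 904 to 2126 of 10960 in RIP-1 and from 185 to 1423 of 10280 in RIP-2.

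The highest-scoring peak of each mRNA list had no partner in the other experiment. In the RIP-1 mRNA list 58 peaks scored 3100 or more. Since 3100 looked like a cap, peaks at that value may be as strong as those above it. The 5 RIP-1 peaks without a RIP-2 partner that had the highest scores reached from 3129 to 3218. They lay on chromosome X from 102632108 to 102633092, chromosome 19 from 49588471 to 49588893, chromosome 3 from 53289851 to 53290130, chromosome 4 from 39699663 to 39700010 and chromosome 6 from 3153939 to 3155289. The 5 RIP-2 peaks without a RIP-1 partner that had the highest scores reached from 2202 to 3100. They lay on chromosome 1 from 214817899 to 214820743, chromosome 6 from 151669845 to 151674887, and chromosome 3 from 150906140 to 150906267, from 37365078 to 37369316 and from 121412587 to 121417776.

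No correlation of scores between the experiments was detected among shared mRNA-list peaks, whose lists hold no fold enrichment to compare. Across the 703 shared RIP-1 peaks, the scores of RIP-1 and RIP-2 had a Spearman rho of 0.0496 (permutation p = 0.188) and a Pearson r of 0.0459 on log10 values (permutation p = 0.223). Peaks are not independent replicates in this correlation. Shared RIP-1 peaks were weaker than unshared ones, with median scores of 69.7 and 81.0 (permutation test, two-sided, p = 1e-05, the smallest possible). For RIP-2 the medians were 81.8 for shared and 79.4 for unshared peaks, a difference that did not pass the test (permutation p = 0.180). In RIP-1 the shared fraction fell from 8.85% in the weakest 10% of the list by score (97 of 1096, 95% CI 7.31 to 10.7) to 0.821% in the strongest 10% (9 of 1096, 95% CI 0.433 to 1.55). The peaks of that strongest 10% were also the widest, with a median of 517 bp against 179 bp in the weakest 10%. In RIP-2 the shared fraction lay between 5.74% and 7.68% in all 10 classes of score.

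**Figure D2:**
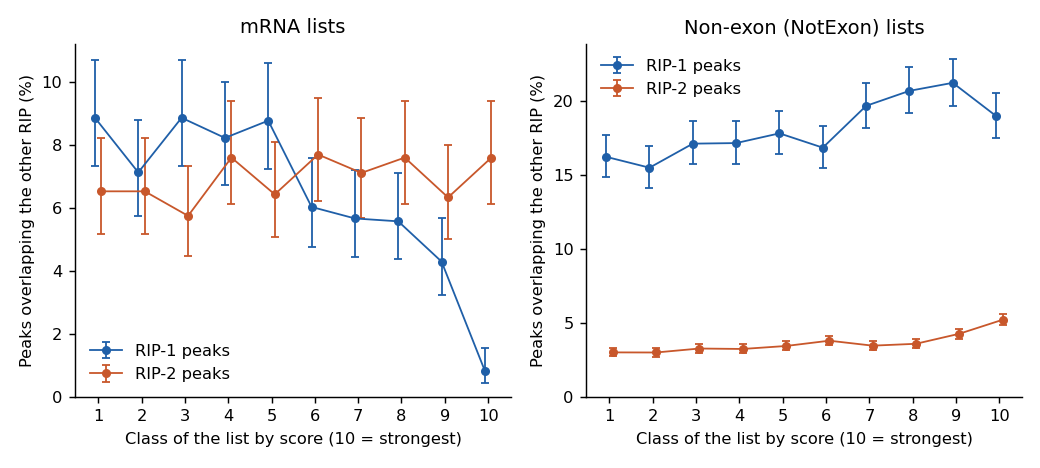
Percentage of peaks that overlap a peak of the other experiment (vertical axis) in 10 equal classes of the list by score (horizontal axis, 10 is the strongest), for the mRNA lists on the left and the non-exon lists on the right. Points are classes of the RIP-1 list (blue) or RIP-2 list (orange) and bars are 95% Wilson intervals; the RIP-1 mRNA list falls from 8.85% to 0.821%, while the RIP-2 mRNA list stays between 5.74% and 7.68%.

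Sharing of mRNA-list peaks was lowest on chromosome 19 among the chromosomes other than Y. There 11 of 665 RIP-1 peaks were shared (1.65%, 95% CI 0.926 to 2.94), against 37 of 327 on chromosome 8 (11.3%, 95% CI 8.32 to 15.2). Chromosomes 22 and 20 had 2.58% (95% CI 1.26 to 5.23) and 3.78% (95% CI 2.12 to 6.64). No chance level was estimated per chromosome, and the share depends on how many RIP-2 peaks a chromosome holds. The RIP-2 mRNA list had 298 peaks on chromosome 19 against 665 in RIP-1, and 353 against 327 on chromosome 8.

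Of the 25797 RIP-1 non-exon peaks, 4679 overlapped a RIP-2 non-exon peak (18.1%, 95% CI 17.7 to 18.6), against 2712 by chance (95% range 2631 to 2795), which is 1.73 times chance (permutation test, one-sided, p = 0.001, the smallest possible). This share depends on the length of the RIP-2 list: with only the strongest RIP-2 peaks, as many as in RIP-1, 1210 RIP-1 peaks were shared (4.69%). Shares of the 2 kinds of list are not directly comparable. With the full lists, chance alone gave 10.5% of RIP-1 peaks for the non-exon lists and 0.616% for the mRNA lists. The factor over chance was 3.71 when at least 50% of both peaks had to overlap and 2.96 when the midpoint of the RIP-1 peak had to lie in a RIP-2 peak. Of the 134094 RIP-2 peaks, 4863 overlapped a RIP-1 peak (3.63%, 95% CI 3.53 to 3.73). Chromosome 19 again had a low value, with 56 of 703 RIP-1 non-exon peaks shared (7.97%, 95% CI 6.19 to 10.2). The RIP-2 non-exon list was sparse there, with 31.4 peaks per Mb against a mean of 43.3, and no chance level per chromosome was estimated. Shared non-exon peaks were slightly stronger than unshared ones, with median scores of 69.1 and 66.5 in RIP-1 and of 86.3 and 80.3 in RIP-2. They were also wider, with medians of 855 and 684 bp in RIP-1 and of 727 and 560 bp in RIP-2 (each of these 4 differences had a permutation p of 1e-04, the smallest possible). A wider peak overlaps others more often by chance. Across the 4679 shared peaks, fold enrichment in RIP-1 and RIP-2 correlated with a Spearman rho of 0.200 and a Pearson r of 0.194 on log10 values (permutation p = 1e-04 for each, the smallest possible). Their scores correlated with a rho of 0.0464 (permutation p = 0.0023) and an r of 0.0837 (permutation p = 1e-04, the smallest possible). Of the 175 RIP-1 peaks with an FDR of 5% or less, 3 were shared, against 6.18 by chance.

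The windows of 100 kb with the most shared RIP-1 non-exon peaks held 5 each, on chromosome 8 from 12300001 to 12400000 and on chromosome X from 64400001 to 64500000. In these windows RIP-1 had 6 and 7 non-exon peaks and RIP-2 had 20 in each, and neither held an mRNA-list peak. There were 32 windows with 4 shared peaks, the first of them on chromosome 1 from 227800001, chromosome 10 from 105000001 and chromosome 13 from 92800001.

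**Figure D3:**
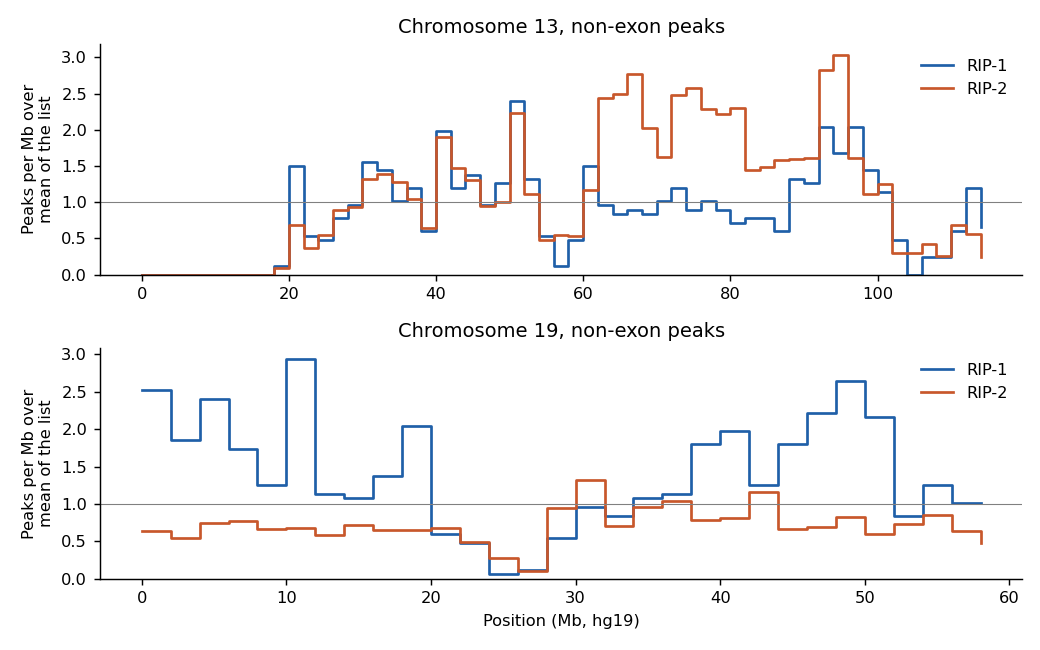
Non-exon peaks per Mb over the mean of their list (vertical axis) in windows of 2 Mb along chromosomes 13 and 19 (horizontal axis, position in Mb, hg19), with RIP-1 in blue and RIP-2 in orange; the grey line marks the mean. From 60 to 84 Mb on chromosome 13, RIP-2 lay at 2.15 times its mean and RIP-1 at 0.965 times, while in the first 20 Mb of chromosome 19 RIP-2 lay at 0.666 times and RIP-1 at 1.84 times. The highest RIP-2 window of chromosome 13, from 94 to 96 Mb at 3.03 times, was also raised in RIP-1, at 1.68 times.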

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

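Tests with thresholds from the FDR, with pieces of at least 100 bp, without chromosomes 1 and 13, with longer moves for the non-exon lists, and of non-exon strength were chosen after the data were seen. Among the alternative values, 29 kept their direction, their side of the threshold and, for counts and factors, stayed within 1.5 times the main value. Another 12 moved further and 3 no longer passed the test. The lists held no overlapping intervals, so merging them could change nothing. The merged values are among the 29 and add no support to them. The same holds for the counts of shared peaks with longer moves, since moves alter only the chance level. For overlap, the count and the factor of 1 setting also rest on the same test and are not separate checks. For mRNA-list sharing the factor over chance was 50.03 when at least 50% of both peaks overlapped, 21.9 when the RIP-1 midpoint lay in a RIP-2 peak, and 27.6 with moves of 50 to 500 kb. Each of these may be raised by the common edges of the mRNA lists, which the moves do not keep. For non-exon sharing it was 3.71 and 2.96 under the first 2 of these settings. The upper 50% by score shortened the mRNA lists to 5480 and 5140 and the non-exon lists to 12898 and 67047 by construction, with 133 and 1443 shared peaks. The strongest RIP-2 non-exon peaks, as many as in RIP-1, shared 1210. At a score of 402 or more, the lowest among RIP-1 non-exon peaks with an FDR of 5% or less, 0 of 541 RIP-1 mRNA-list peaks overlapped the 56 of RIP-2, and chance also gave 0, so few peaks remain to test. RIP-1 non-exon peaks with an FDR of 5% or less shared 3, which is 0.485 times chance (permutation p = 0.961); the cause was not tested. No paired analysis was possible because each list is a single call per experiment without values per library. Alternatives that need gene names, an hg19 annotation or its sequence, and redrawing peaks inside their own exons, were not run. Unknown depth limits every comparison of list lengths and scores between the experiments.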

Other observations

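The tests of steps in the fold enrichment, of a tail of weak peaks and of gene-dense chromosomes, the stretches of chromosomes and the added FDR, distance and score-class values were chosen after the data were seen. Non-exon peaks of RIP-2 were crowded in some stretches more than those of RIP-1. On chromosome 13 from 60 to 84 Mb, RIP-2 had 2237 non-exon peaks, 93.2 per Mb or 2.15 times the mean of its list, while RIP-1 had 193, or 0.965 times its mean. The mRNA lists had 31 peaks each in this stretch. Crowding on chromosome 13 was not confined to RIP-2, since its densest window of 2 Mb, from 94 to 96 Mb, had 3.03 times the mean in RIP-2 and 1.68 times in RIP-1. On chromosome 1 from 220 to 240 Mb, RIP-2 had 2.20 times its mean and RIP-1 1.47 times. On chromosome X from 100 to 150 Mb, the values were 1.64 and 1.20 times. The first 20 Mb of chromosome 19 went the other way, with 0.666 times the mean in RIP-2 and 1.84 times in RIP-1.

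The strongest non-exon peaks also differed. In RIP-1 the highest fold enrichment was 178.68, on chromosome 1 from 153953535 to 153956537 with an FDR of 2.53%, and a peak with a fold enrichment of 73.4 lay beside it from 153957731 to 153959239. The next were on chromosome 15 from 38762254 to 38763051 (fold enrichment 94.5) and on chromosome 7 from 96323931 to 96324772 (fold enrichment 93.7). In RIP-2 the highest was 56.9, on chromosome 3 from 303604 to 304308, followed by 49.9 on chromosome 4 from 52660720 to 52661430, both with an FDR of 100%. In RIP-2 a higher score went with a higher FDR. The median FDR was 77.1% in the lower 50% of the list by score and 100% in the upper 50%, and every peak with a score above 89.5 had an FDR of 100%. This FDR rests on the control library, whose kind and depth are unknown, so it was not read as a property of the peaks. Among shared non-exon peaks, the highest lower fold enrichment was on chromosome 2 from 160121848 to 160122600, with 14.8 in RIP-1 and 22.9 in RIP-2.

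The first pattern weighed was the length of the RIP-2 non-exon list. If its peaks came from unspliced RNA of the genes whose exons hold RIP-1 peaks, RIP-2 peaks were predicted to crowd near RIP-1 mRNA-list peaks. All RIP-2 peaks together lay within 10 kb of one 1.01 times as often as after moves of 1 to 5 Mb (8860 against 8751, 95% range 8558 to 8932). Near the mRNA-list peaks of the other experiment, RIP-2 non-exon peaks alone gave 0.801 and RIP-1 non-exon peaks 1.41 times chance, and near those of their own call 1.12 and 2.02 times. No crowding of RIP-2 non-exon peaks within 10 kb of RIP-1 mRNA-list peaks was therefore seen. A reach of 10 kb can miss the farther parts of long genes, and moved peaks can land in equally gene-rich regions. Unspliced RNA was therefore not ruled out. A tail of weak peaks could not be judged as the cause, because the ratio of the lists depended on the score chosen. At a score of 117.5 or more, the level of the strongest 10% of RIP-1, RIP-2 had 12.1 times as many peaks as RIP-1 (31157 against 2582, 95% CI 11.6 to 12.6). Over the whole lists it had 5.20 times as many, and at a score of 402 or more it had 439 against 207. Scores also rest on the depth and control of each call, which are unknown. Fragments spread over the genome without regard to these transcripts, such as carried-over DNA, would give a ratio near 1, and the pooled ratio was 1.01. That ratio pools both RIP-2 lists, and the non-exon list alone lay below chance (6472 against 8077, 95% range 7924 to 8261). Its strongest 10% lay at 0.697 times chance (565 against 811, 95% range 758 to 869). A deficit in the non-exon list and an excess in the mRNA list therefore balance in the pooled ratio, so even placement of the non-exon peaks was not shown. The control and depth of the calls stay open. Both experiments used the same wild-type cells, so the design gives no biological difference to test.

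The second pattern was the small number of mRNA-list peaks shared between the experiments. A set of strong common peaks diluted by weak ones would be shared most often at the top, but the strongest 10% of RIP-1 peaks was shared 0.117 times as often as the others (95% CI 0.0607 to 0.225). Sharing was also low outside the gene-dense chromosomes. Without chromosomes 16, 17, 19, 20 and 22 the shared part was 7.11% (618 of 8695, 95% CI 6.59 to 7.67) against 6.41% with them. Most RIP-1 peaks lay on the chromosomes that were kept, so the share could rise only a little. The test could therefore not have favoured poor measurement of the gene-dense chromosomes in RIP-2, and no conclusion on it was drawn. A difference in control or depth between the calls stays open, as does a difference in what the antibody recovered.

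The third pattern was that many fold enrichment values below 12 fell on equal steps, although in RIP-1 most did not. The step was fitted on the odd-numbered chromosomes and tested on the even-numbered ones, X and Y, with a tolerance of 0.005. Only a limited range of steps was searched. In RIP-1 30.2% of the values lay on multiples of 0.4145, 12.5 times chance, and in RIP-2 68.8% lay on multiples of 0.4818, 33.2 times chance. Even multiples made up 59.4% of these in RIP-1 (95% CI 57.8 to 61.0) and 61.4% in RIP-2 (95% CI 60.9 to 61.9). Over all chromosomes the most frequent were 18 and 16 steps. A candidate explanation for the values on a step is that many of these peaks rest on about 16 to 18 reads over a constant background, with both mates of a read pair counted. That number of reads depends on the range of steps searched. No biological explanation was tested.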
